A study of Mus musculus with 2 samples.

How the data were processed

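The series held 2 biological replicates of H3K27ac chromatin immunoprecipitation followed by sequencing (ChIP-seq) from mouse kidney at embryonic day 14.5. H3K27ac is the acetylation of lysine 27 of histone H3, a mark found at active promoters and enhancers. Per the labels, the kidneys came from pooled embryos of both sexes, and each replicate was a separate biological sample. Both belonged to 1 group, so no comparison between conditions was possible. What could be compared was the replicates with each other, the lists made from both replicates with each replicate, and regions or gene lists with the rest of the genome.

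4 peak lists on the mm10 build were used. The deposited descriptions state that 1 list was called on each replicate alone, that 1 came from both replicates pooled, and that 1 held the replicated peaks. They also name alignments and a control among the inputs. The peak caller, its version and the aligner are not given in the sources used here. Each line of a list held a position, a summit, an enrichment ratio, a −log10 p and a −log10 q. The enrichment ratio is the authors' own value for that peak, computed against the control, per the deposited descriptions. It was used only to describe, rank or filter peaks within a list, since lists of different depth do not share a scale. The −log10 p and −log10 q values were deposited by the authors for each peak. The lowest −log10 p was between 2.00 and 2.06 in the 4 lists, which is a p of about 0.01, and no q threshold was visible: the lowest −log10 q was between 0.225 and 0.397. The share of peaks with a q above 0.05 was 24.1% in replicate 1, 7.67% in replicate 2, 6.55% in the pooled list and 0.895% in the replicated list. All 43898 peaks of the replicated list were found with the same position and values among the 78529 peaks of the pooled list. The files gave no read counts, so the depth of each replicate is unknown, and a place without a peak cannot be told from a place with too few reads. Intervals of shares are exact binomial 95% intervals, and intervals of odds ratios are 95% intervals from a normal approximation on the log scale. They cover counting error over peaks, genes or windows only. Signal tracks and the control libraries were not analysed here.

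Coordinates of the lists were checked against the chromosome lengths of the mouse GRCm38 assembly, which mm10 names, and gene models came from GENCODE mouse release 21 of the same assembly. A promoter was the region within 1 kb of the transcription start site (TSS) of any protein-coding transcript. A gene's strongest promoter peak could therefore lie at a start inside the gene, away from its 5′ end, as at Pecam1 and Impact. There were 21911 protein-coding genes. 2 non-coding genes of the fixed lists were added, which made 21913 genes. Peaks that overlapped a promoter were counted as promoter peaks, and other peaks were placed by their summit in exons, introns or intergenic sequence. Overlap needed 1 bp unless stated otherwise. Random placements moved every peak within its chromosome, outside assembly gaps of at least 1000 bp, 100 times.

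25 gene lists were fixed before the data were examined. Aldh1a2 was in the renal stroma and retinoic acid lists, and no other gene was in more than 1. 24 lists were tested, and the list of Y-linked genes with Xist was read gene by gene. The share of list members with a replicated promoter peak was compared with that of all other genes by a two-sided Fisher's exact test. For distal acetylation, bases covered by replicated peaks within 50 kb of each gene's 5′ end were summed, leaving out bases within 2.5 kb of any protein-coding TSS. The median of a list was placed among 10000 random lists of the same size, matched in 5 classes on the number of TSS in the window, and a two-sided permutation p was taken. The smallest p this can give is 0.0002. Distal peaks were also joined when 12.5 kb or less apart, and the resulting domains were ranked by the bases their peaks covered. 26 consensus motifs were counted in 500 bp windows at the summits of distal peaks and in as many control windows outside all peaks, from the same chromosomes and matched on GC content in steps of 2%. These shares were compared with a two-sided Fisher's exact test. All adjusted p-values are Benjamini-Hochberg values over the lists or motifs of that test, with a threshold of 0.05. Genes, peaks and windows are not biological replicates, and neighbouring genes can share a peak, so these p-values describe the genome of these pools and not variation between animals.

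The genes named in the text followed a rule fixed before the data were examined. In each list these were the 2 members with the largest and the 2 with the smallest enrichment of their strongest replicated promoter peak, up to 4 in all. A member without a peak counted as smallest, and ties were broken alphabetically. To these were added Six2, Pax2, Wt1, Ret, Gdnf, Foxd1, Hnf1b, Hnf4a, Nphs1, Alb, Foxg1 and all Hox genes, the protein-coding genes nearest to the 20 longest domains, and the 10 genes of any type with the most distal covered bases. Other genes named in the text were chosen after their values were seen.

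The scripts were tested on simulated data. For the overlap of replicates, 62258 peaks were tested, of which a part was planted in a second list with a small shift. 100% of the planted peaks were found, which the small shift made certain, and 0.875% of the other peaks overlapped. For promoter peaks over 21913 genes, 90.0% of simulated lists with a share of 95% and 80.0% of those with a share of 5% were called, with 0 of the unchanged lists. For distal coverage over 21913 genes, 100% of lists drawn from the top 25% of genes and 0% of random lists were called. The top lists were drawn by the same values that were then tested, which made their calls all but certain. Of 26 motifs, a planted SIX-type consensus was called with a difference of 1.85 percentage points where 2 were planted, and 0 other motifs were called.

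The alternatives were a stricter q (1e-05) or enrichment (4), other overlaps, equal numbers of top peaks, promoter windows of 500 bp and 2.5 kb, distal windows of 20 and 100 kb, joining within 4 kb or not at all, motif windows of 200 and 1000 bp, the reversed consensus as a control, the pooled list, each replicate list alone, and a background of the 10748 genes with at least 55% GC within 500 bp of the 5′ end. A list made from 1 replicate alone stands for leaving out the other. Added after the data were examined were a test on the 18764 genes with no other TSS within 2 kb, control windows of which at most 50% was repeat, an odds ratio divided by that of the reversed consensus, and the overlap of replicates by peak strength. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.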

Results

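H3K27ac ChIP-seq was collected from mouse kidneys of embryonic day 14.5, a stage at which nephron progenitors, the branching ureteric bud, the stroma and the first nephrons lie side by side. There was 1 group of 2 biological replicates, each a pool of embryos. Replicate 1 had 62262 peaks over 26.6 Mb and replicate 2 had 112159 peaks over 53.4 Mb, a mean of 87210.5 ± 35282.5 peaks (SD, n = 2). The median peak width was 288 ± 5.66 bp (SD, n = 2). The pooled list had 78529 peaks and the replicated list had 43898 peaks over 35.0 Mb. Read depth is unknown for both replicates.

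The first question was how far the replicates marked the same places. The strongest peaks were shared: all 6227 peaks in the top 10% of replicate 1 by enrichment, and 97.4% of those in the top 10% of replicate 2, overlapped a peak of the other replicate. In the weakest 10%, 46.5% of replicate 1 and 9.68% of replicate 2 peaks did. Promoter peaks were shared more often than other peaks, with 89.8% against 58.0% in replicate 1 and 63.1% against 24.8% in replicate 2. They were also stronger, with a median enrichment of 4.17 against 3.16 in replicate 1 and 5.22 against 3.63 in replicate 2. Location and strength were not separated. Over all peaks, 66.3% of replicate 1 (95% exact interval 66.0% to 66.7%) and 32.1% of replicate 2 (31.8% to 32.4%) overlapped. Random placements gave 4.23% ± 0.0764 and 2.20% ± 0.0410 (SD over 100 placements). Covered bases had a Jaccard index of 31.8%, against 0.774% at random. Across 41294 overlapping pairs the Spearman correlation of enrichment was 0.559, a description across peaks, which are not independent replicates. Each replicate 1 peak was paired with the replicate 2 peak it overlapped most, so a wide replicate 2 peak could enter several pairs. With overlaps of at least 50% of both peaks, the shares were 29.8% and 16.5%.

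**Figure D1:**
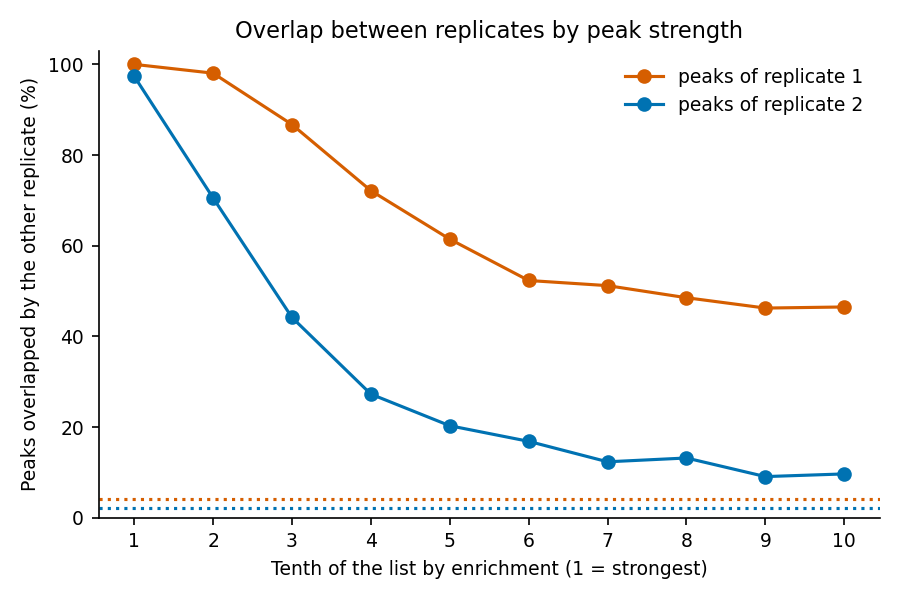
Percent of peaks overlapped by the other replicate (y axis) in each of 10 equal parts of a replicate's list by enrichment (x axis, 1 is the strongest), with dotted lines for the mean of 100 random placements. Overlap was 100% and 97.4% in the strongest part and 46.5% and 9.68% in the weakest, for replicates 1 and 2.

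The lists made from both replicates were then set against each replicate. Of the replicated peaks, 99.1% overlapped a peak of replicate 2, 76.5% a peak of replicate 1 and 75.7% both. Of the pooled peaks, 89.3% overlapped replicate 2, 49.3% replicate 1 and 43.1% both. The replicated list held 55.9% of the pooled peaks. The rest of the replicated list lacked a peak in the deposited list of 1 replicate or both, and what the replicated list adds beyond the 2 lists is not stated. With at least 50% of both peaks required, the share found in both replicates was 46.0% of the replicated list.

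Acetylated regions lay at promoters far more often than chance. Of the replicated peaks on the main chromosomes, 14227 (32.4%) were at promoters, 8.92-fold over the 3.63% ± 0.0907 of random placements (SD over 100). Intergenic sequence held 12640 peaks (28.8%), below the 57.2% ± 0.240 of random placements. Introns held 35.5% (random 36.0% ± 0.224) and exons 3.25% (random 3.20% ± 0.0810), each within 3 SD of random. Promoters were counted first, so their large share lowers the other shares. These values therefore do not show that peaks outside promoters lay in introns or exons at random. In replicate 1, replicate 2 and the pooled list introns held 38.9%, 43.5% and 41.1%. Promoter peaks had a median enrichment of 6.24 and a median width of 731 bp, and the others 4.08 and 502 bp. In the replicates' own lists the promoter share was 26.2% and 18.95%, 22.6% ± 5.12 (SD, n = 2), and it was 23.4% in the pooled list. Among replicated peaks with a q of 1e-05 or less it was 41.7%.

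Promoters of genes of the embryonic kidney's progenitors, stroma and vessels carried the mark. Of 14 nephron progenitor genes, 13 had a replicated promoter peak, as had 13 of 14 renal stroma genes and 12 of 13 endothelial genes, against 48.9% of other genes. The adjusted p was 0.00236, 0.00236 and 0.00401 (Fisher's exact test). None of these lists passed among genes with GC-rich promoters, where more of the other genes were marked. In the replicates' lists the shares were 92.9% ± 0, 96.4% ± 5.05 and 88.5% ± 5.44 (SD, n = 2). Among nephron progenitor genes the strongest peak lay at Sall1, a zinc finger factor needed for kidney formation (enrichment 24.5, chromosome 8, 89039329 to 89046543), then at Pax2, a paired-box factor of the nephron lineage (21.8). Osr1 had 3.57, and Crym was the member without a replicated peak. In the replicates' own lists Crym had a peak in replicate 1 only (3.37) and Osr1 in replicate 2 only (4.88). The equal shares of the replicates thus did not hold the same members. Among stroma genes Pbx1, a homeodomain cofactor, had 36.3 and Meis1, another such cofactor, 23.1, while Ntn1 had 3.01 and Acta2, smooth muscle actin, had no replicated peak. The strongest endothelial values were lower, with Pecam1 at 6.54 and Esam at 5.74, while Sox17 had 3.16 and Tie1 none. The counted peaks of Osr1, Ntn1, Pecam1 and Esam lay at a transcript start inside the gene, away from its 5′ end. With peaks of a q of 1e-05 or less, 69.2% of endothelial genes were marked and the list did not pass (adjusted p = 0.121, Fisher's exact test), nor did it at an enrichment of at least 4.

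Mature tubule genes were marked less often than other genes. Of 17 mature tubule genes 3 had a promoter peak (17.6%, adjusted p = 0.0195, Fisher's exact test), namely Hnf1a with an enrichment of 15.6, Lrp2, the endocytic receptor megalin, with 3.06, and Pdzk1 with 2.98. Hnf4a, a proximal tubule regulator, and the water channels Aqp1 and Aqp2 had none. In between lay early nephron genes with 12 of 16, podocyte genes with 9 of 14 and ureteric bud genes with 10 of 16, none of which passed the test (adjusted p = 0.0600, 0.319 and 0.338, Fisher's exact test). Jag1, a Notch ligand, had 16.3 and Hey1, a Notch target, 16.2, whereas Fgf8 and Hes5 had no replicated peak. Among podocyte genes Foxc2 had 26.99 and Vegfa 22.8, but Nphs1, which encodes nephrin of the slit diaphragm, and Lmx1b had none. Among ureteric bud genes Emx2 had 20.8 and Etv4 16.8, and Calb1 and Krt19 had none. Ret, the receptor of the ureteric bud tip, had no replicated promoter peak and a value of 2.45 in replicate 1. Ureteric bud genes passed in replicate 2 alone, with 14 of 16 (adjusted p = 0.0188, Fisher's exact test). In replicate 1 and in replicate 2 alone, 14 and 15 of 16 early nephron genes were marked and the list passed the test (adjusted p = 0.00685 and 0.00513, Fisher's exact test). Mature tubule genes had 3 and 6 of 17, and the list did not pass in replicate 2 (adjusted p = 0.118, Fisher's exact test) or among GC-rich promoters (40%).

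Lists of other tissues and cell types were marked at few promoters. None of 12 forebrain genes (Foxg1, Dlx1 and Dlx2 among them) and none of 13 hepatocyte genes (Alb and Afp among them) had a replicated promoter peak, nor did any of 1134 olfactory receptor genes such as Olfr1 and Olfr10. The adjusted p was 0.00236 for forebrain and 0.00151 for hepatocyte genes, and for olfactory receptors it was too small for the software to hold (Fisher's exact test). Muscle genes had 1 of 13 (Mylpf, 8.95, in a peak shared with the promoter of Tbc1d10b), peripheral neuron and glia genes 1 of 13 (Elavl4, 6.31), adrenal and gonad genes 1 of 11 (Star, 3.47), germ line and pluripotency genes 1 of 11 (Dazl, 5.29) and macrophage genes 2 of 13 (Aif1, 3.26, and Cd68, 3.06). Each passed the test (adjusted p = 0.00762, 0.00762, 0.0190, 0.0190 and 0.0322, Fisher's exact test). Erythroid genes had 3 of 13 (Nfe2, 5.50, Tal1, 5.43, and Klf1, 2.55) and did not pass (adjusted p = 0.118, Fisher's exact test). Adgre1, C1qa, Alas2, Ckm, Cyp11a1 and Ddx4 had no promoter peak in any of the replicated or single replicate lists. The replicates differed for macrophage genes, of which 1 of 13 was marked in replicate 1 and 7 of 13 in replicate 2, where the list did not pass the test (adjusted p = 1, Fisher's exact test). Peripheral neuron genes had 1 and 5 of 13, and adrenal and gonad genes 1 and 3 of 11, and neither list passed in replicate 2 (adjusted p = 0.303 and 0.104, Fisher's exact test). With promoter windows of 2.5 kb muscle, macrophage and adrenal genes did not pass, in the pooled list muscle and peripheral neuron genes, and on genes with no other TSS within 2 kb, a test added after seeing the data, macrophage and pluripotency genes. Among GC-rich promoters the hepatocyte, muscle, pluripotency, macrophage and olfactory receptor lists did not pass, with 1 to 5 members left in each.

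Genes used in most cells were marked, with values in the upper part of the list. All 14 housekeeping genes had a promoter peak (adjusted p = 0.000361, Fisher's exact test), from Actb with an enrichment of 42.0 and Ywhaz with 40.6 to B2m with 6.11 and Sdha with 5.90. Cell cycle genes had 12 of 14, among them Aurkb (15.9) and Mcm6 (12.2). Imprinted genes had 12 of 14, among them Impact (14.4) and Grb10 (13.2). Bub1, Mcm3, Dlk1 and Meg3 lacked a replicated promoter peak. Both lists had an adjusted p of 0.0117 (Fisher's exact test). Replicate 1 marked 12 and replicate 2 all 14 genes of each list, and Dlk1 had a peak in both replicates (3.59 and 3.17). The imprinted list did not pass with peaks of a q of 1e-05 or less (71.4%, adjusted p = 0.0787, Fisher's exact test) or an enrichment of at least 4. Retinoic acid genes had 7 of 14, with Rara at 19.5 and Rarg at 15.4 and no peak at Aldh1a1 or Aldh1a3, and renin-angiotensin genes had 1 of 7 (Atp6ap2, 5.19), with none at Ace or Ace2. Neither passed (adjusted p = 1 and 0.151, Fisher's exact test). In total 8 lists were marked more often than other genes, 9 less often and 7 could not be told apart from them. Among genes with GC-rich promoters, 71.7% to 71.8% of those outside a list were marked. There the nephron progenitor, stroma, endothelial, cell cycle, housekeeping and Hox 9 to 11 lists stood at 100%, but most lists kept 9 or fewer members, no list passed as marked more often and 4 passed as marked less often.

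**Figure D2:**
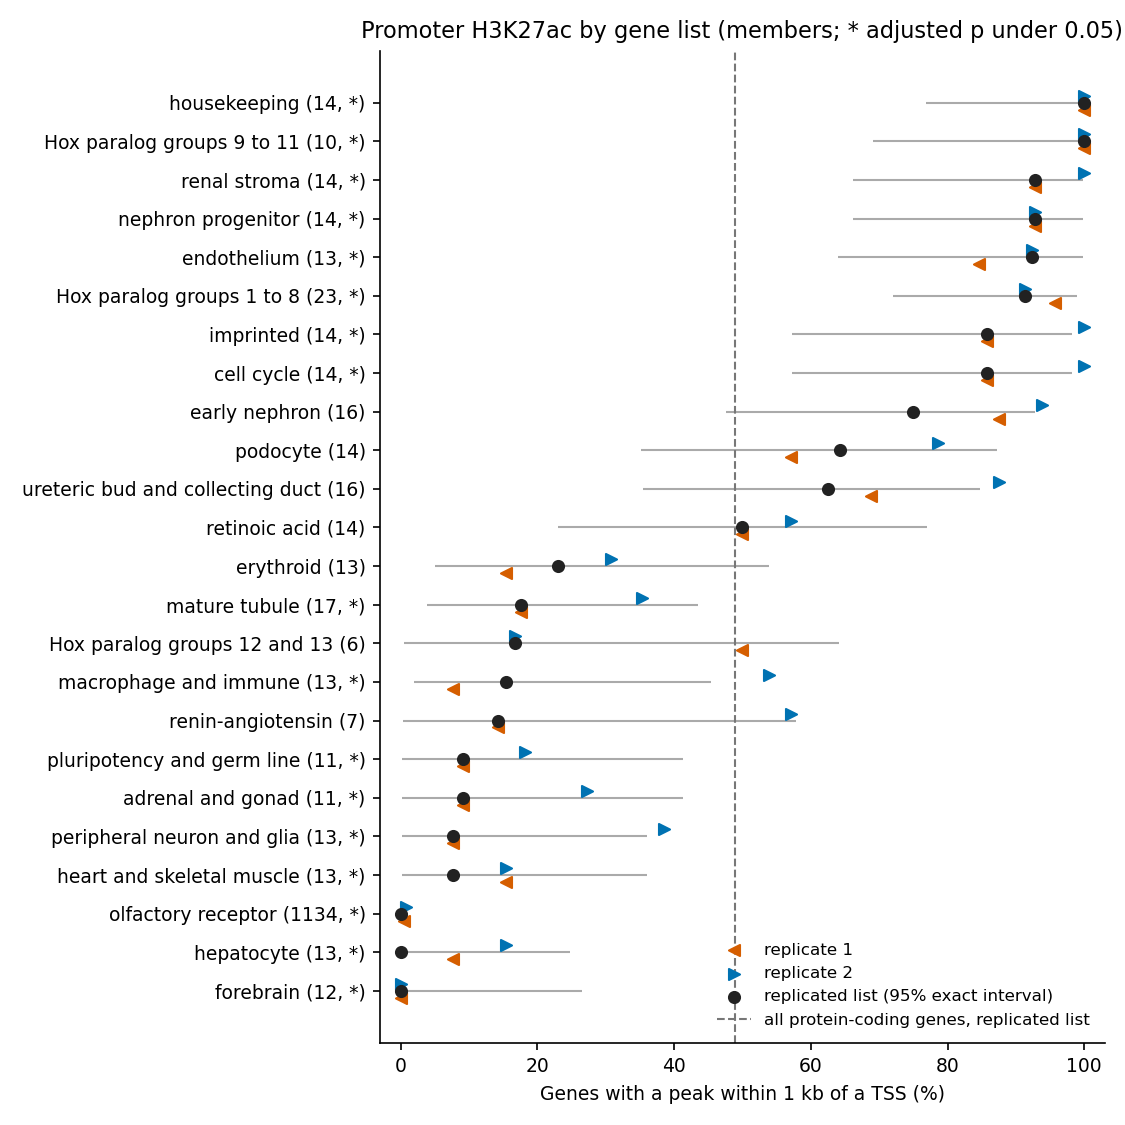
Percent of the genes of each list with a peak within 1 kb of a TSS (x axis) for the 24 tested lists (y axis, number of members in brackets, asterisk for an adjusted p under 0.05), with points for the replicated list with its exact 95% interval and for each replicate list. The dashed line marks the 48.9% of all protein-coding genes, with nephron progenitor and stroma genes to its right and forebrain and hepatocyte genes at 0.

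The Hox clusters, whose genes set position along the body axis, were acetylated over long stretches, with few replicated promoter peaks at the posterior ends. Of 23 genes of paralog groups 1 to 8, 21 had a promoter peak, as had all 10 of groups 9 to 11 (adjusted p = 0.000314 and 0.00236, Fisher's exact test). Of the 6 genes of groups 12 and 13 only Hoxd12 had one, with an enrichment of 7.0 (adjusted p = 0.251, Fisher's exact test). Among genes with GC-rich promoters groups 1 to 8 and 9 to 11 did not pass, and groups 12 and 13 passed as marked less often. Hoxa13, Hoxb13, Hoxc12, Hoxc13 and Hoxd13 had none, although replicate 1 marked 3 of the 6, with weak peaks at Hoxc13 (3.47) and Hoxd13 (2.95). Groups 9 to 11 ranged from Hoxa9 with 10.9 and Hoxc11 with 11.2 to Hoxa10 with 21.3 and Hoxd9 with 23.3. The anterior Hoxb1 and Hoxd1 also lacked a replicated peak. 1 peak of 65538 bp (chromosome 11, 96281959 to 96347496, enrichment 32.0) covered the promoters of Hoxb3, Hoxb4, Hoxb5, Hoxb6, Hoxb7 and Hoxb8, so the 21 marked genes of groups 1 to 8 rested on 16 peaks and were not independent. Replicated peaks covered 69.1% of the HoxA cluster, 50.5% of HoxB, 49.4% of HoxC and 57.9% of HoxD, counted with 5 kb on each side. In the replicates they covered 71535 ± 15491 bp, 90086 ± 9399 bp, 56098 ± 15275 bp and 56640 ± 11288 bp (SD, n = 2).

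**Figure D3:**
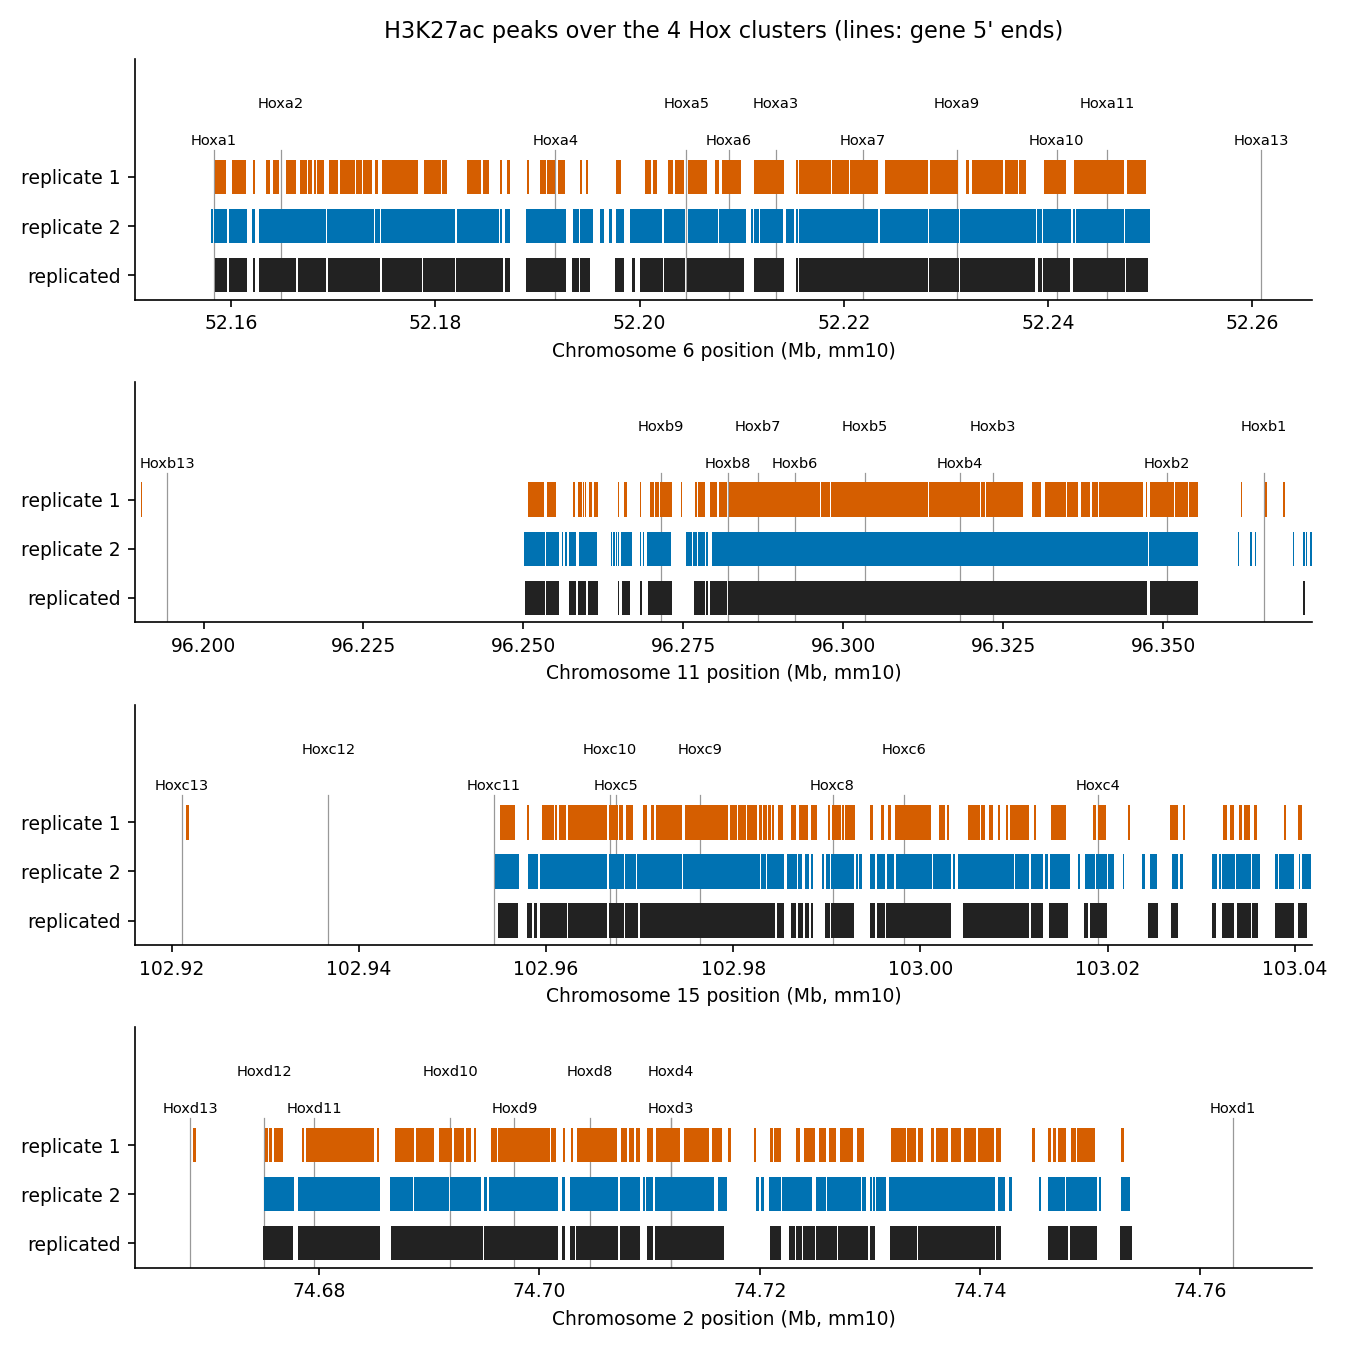
Peaks of replicate 1, replicate 2 and the replicated list (blocks) along the 4 Hox clusters (x axis, mm10 position in Mb), with grey lines at gene 5′ ends. Replicated peaks cover 69.1%, 50.5%, 49.4% and 57.9% of HoxA, HoxB, HoxC and HoxD, and the replicated list has none at Hoxa13, Hoxb13, Hoxc12, Hoxc13 or Hoxd13.

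Single loci showed the extent of the mark around nephron progenitor and stroma regulators. Six2, a homeodomain factor that keeps nephron progenitors undifferentiated, had its strongest replicated peak at its own promoter (chromosome 17, 85687088 to 85688089, enrichment 7.93, and 5.68 and 11.02 in replicates 1 and 2). Within 100 kb of its 5′ end lay 12 replicated peaks, 9 of them intergenic. A pair of intergenic peaks lay 59.4 kb and 61.4 kb upstream (85747120 to 85747915, enrichment 5.93, and 85749005 to 85749882, enrichment 5.90). The first overlapped a peak in replicate 1 (2.76) and in replicate 2 (9.04), whereas the second had a partner only in replicate 2 (6.70). Foxd1, a forkhead factor of stromal progenitors, had 9 replicated peaks within 100 kb, among them intergenic ones 11.6 kb (enrichment 10.4) and 37.0 kb downstream (12.1). Pax2 had 19 and Wt1, a zinc finger factor of progenitors and podocytes, had 22. Gdnf, the ligand of Ret, had 3, 1 of them at its promoter with 9.44. Around Ret there were 3, none closer than 58.8 kb. Hnf1b, a homeodomain factor of the early nephron and ureteric bud, had a promoter value of 11.4, and Wt1 15.4.

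**Figure D4:**
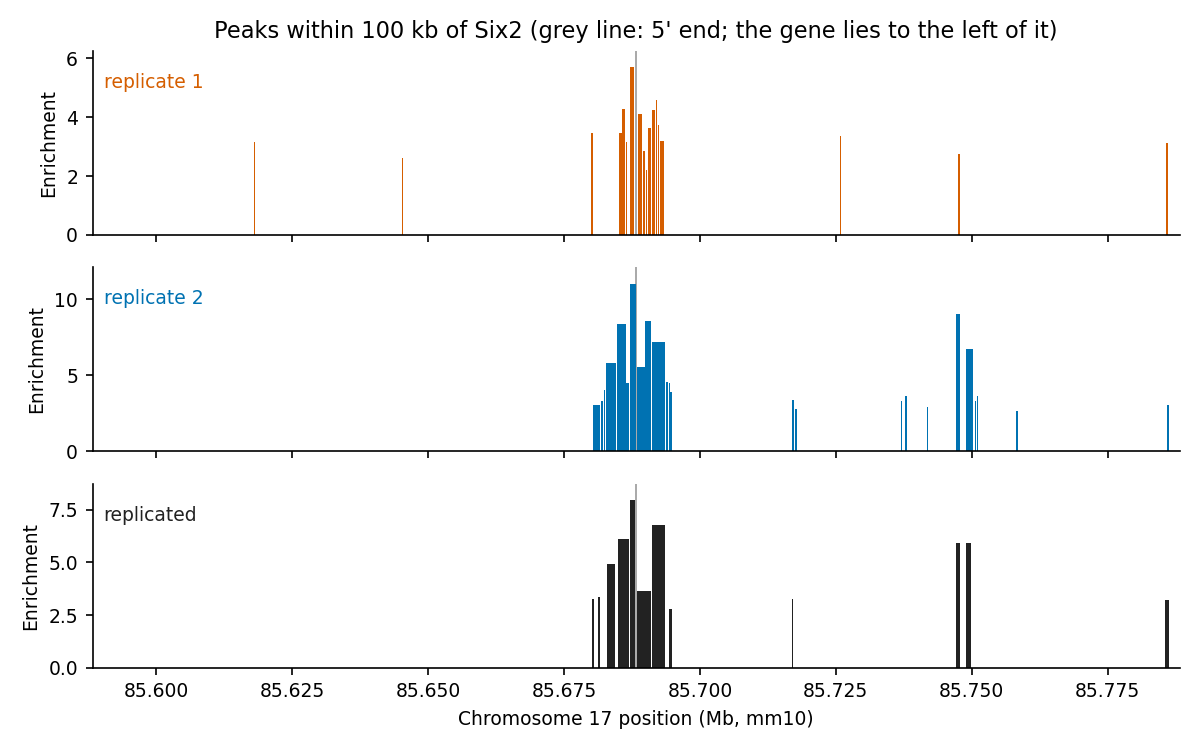
Peaks within 100 kb of the Six2 5′ end (x axis, mm10 position on chromosome 17 in Mb) with their enrichment (y axis, a separate scale for each list, as values are comparable only within a list). Peaks cluster at the gene, and a further pair of replicated peaks lies 59.4 and 61.4 kb upstream.

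Distal acetylation near the same lists was compared with matched random lists. 10 of 24 lists had more covered bases than random lists. Fewer could not be tested for most lists, because the median gene had 0 distal bases. Of olfactory receptor genes 3.70% had any, against 50.2% in random lists, and this list passed as lower in 4 of 7 alternatives but not in the main setting. Ureteric bud genes had a median of 3800 bp, nephron progenitor genes 2682 bp, renal stroma genes 2156.5 bp and early nephron genes 1381 bp, where the random median was 0 (adjusted permutation p = 0.0012, 0.0016, 0.0016 and 0.0171). In replicates 1 and 2 the median was 2638.5 and 6121 bp for ureteric bud, 1143.5 and 4325.5 bp for nephron progenitor, 926.5 and 4710.5 bp for renal stroma and 1636.5 and 2155 bp for early nephron genes. Renal stroma did not pass in replicate 1 alone (adjusted permutation p = 0.0508) or with 100 kb windows. Housekeeping genes had 1920 bp, imprinted genes 2290.5 bp and retinoic acid genes 1804.5 bp (adjusted permutation p = 0.0178, 0.00274 and 0.0138). The Hox lists had 23034 bp in groups 1 to 8, 12200 bp in groups 9 to 11 and 9451 bp in groups 12 and 13, each with the smallest p the permutations can give, 0.0002, and an adjusted permutation p of 0.0012. With 20 kb windows the housekeeping (255 bp) and Hox 12 and 13 lists (729 bp) did not pass, nor did housekeeping genes in the pooled list. Windows of neighbouring Hox genes overlap, so these genes were not independent, and most genes of groups 12 and 13 had distal bases without a promoter peak, such as 11502 bp at Hoxd13. Podocyte, endothelial, muscle and mature tubule genes had medians of 845, 1124, 1169 and 361 bp and did not pass (adjusted permutation p = 0.134, 0.100, 0.100 and 0.658). Cell cycle, hepatocyte, pluripotency, macrophage, erythroid, peripheral neuron, forebrain, adrenal, renin-angiotensin and olfactory receptor lists had medians of 381 bp or less and did not pass.

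The longest distal domains were described without a test. Joining distal peaks gave 12572 domains with a median of 817 covered bp. The longest covered 53854 bp in 33 peaks on chromosome 12 (79831100 to 79950493), overlapped no protein-coding gene, and lay 162520 bp from the nearest protein-coding 5′ end, that of Zfp36l1. The next covered 47186 bp on chromosome 2 (30636131 to 30726432), 41091 bp from Cstad. The third covered 42406 bp on chromosome 7 (142505398 to 142591074) and held the 5′ end of Mrpl23. The fourth, 41261 bp, lay over Zmiz1 and the fifth, 38872 bp, over Msi2. All 20 longest domains had peaks in replicate 1 as well, which says little, since each joined at least 12 replicated peaks. The first 2 covered 45982 ± 19448 and 43640 ± 11746 bp in the replicates (SD, n = 2). Further down lay domains nearest to Igf2r (26285 bp), Notch2 (26102 bp), Hmga2 (25735 bp) and Bahcc1 (25060 bp). The genes of any type with the most distal covered bases within 50 kb were the non-coding Gm14486 (47186 bp, chromosome 2), Mrpl23 (43998 bp) and the non-coding 9430078K24Rik (42092 bp, chromosome 12). Then came Gm5654, Gm14488, Nctc1, Mir3089, 2900052L18Rik, Bahcc1 and Hoxb6 with 42071 to 36422 bp. Several shared a domain: 9430078K24Rik and Gm5654 lay in the first, Gm14486, Gm14488 and Mir3089 in the second, and Mrpl23 and Nctc1 in the third. Only protein-coding TSS were left out, so promoters of non-coding genes could count as distal. The nearest gene is a position and says nothing of which gene a domain acts on. The list of longest domains depended on the joining distance, with 6 of the 20 among the longest at 4 kb.

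Distal peaks were richer than control windows in the consensus sequences of several factor families. Of 27601 windows, 2.51% held a SIX-type consensus against 1.66% of control windows (odds ratio 1.53, adjusted p = 8.19e-12, Fisher's exact test). The PBX-HOX consensus was at 2.37% against 1.48% (1.62, adjusted p = 1.12e-13), TEAD at 8.80% against 6.42% (1.40, adjusted p = 6.24e-25), forkhead (FOX) at 7.34% against 5.28% (1.42, adjusted p = 1.39e-22) and the E-box CAGCTG at 33.4% against 26.3% (1.40, adjusted p = 4.55e-72, Fisher's exact test for each). HNF1, bound by the HNF1 factors of nephron tubules, had the largest odds ratio, 3.77, but on 24 against 6 windows (95% interval 1.59 to 8.96, adjusted p = 0.00265, Fisher's exact test). In all, 16 of 26 motifs were more frequent, among them MEF2 (1.97), ETS (2.32), TFAP2 (1.32), KLF-SP (1.31), PU.1 (1.35), AP-1 (1.2), NFI (2.43), the PAX half-site (1.37), the nuclear receptor consensus (1.08) and posterior HOX (1.06). REST was less frequent (0.728, adjusted p = 0.00654, Fisher's exact test). Its ratio against the reversed consensus in the same windows, a different measure, was 4.20. GATA, MEIS, TCF-LEF, HNF4, SOX, CTCF, NRF1, grainyhead and the E-box CACGTG did not pass, with odds ratios from 0.794 (CTCF) to 1.91 (NRF1). A consensus match is no evidence of binding. Control windows held more repeats than peak windows (29.1% against 12.9% of bases) and fewer CpG pairs, a C followed by a G (6.81 against 7.77 per window). With control windows of at most 50% repeat, an alternative added after seeing the data, the nuclear receptor consensus turned to 0.939. Against the reversed consensus in the same windows the ratio was 0.930 for SIX-type, 0.767 for FOX, 0.252 for ETS and 0.697 for the PAX half-site. It was 1.69 for SOX and 34.6 for CTCF, and PBX-HOX and TEAD were more frequent than their reversals. Control windows do not enter that ratio, which compares a consensus with its reversal, so it is no test of peaks against controls. With 200 bp windows AP-1 (0.997) and KLF-SP (0.933) turned, HNF1, PU.1, NFI, ETS, posterior HOX, the PAX half-site and the nuclear receptor consensus did not pass, and 7 motifs were more frequent. By the ratio over that of the reversed consensus, added after seeing the data, posterior HOX turned (0.881), HNF1 and the PAX half-site did not pass, and 8 were more frequent.

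**Figure D5:**
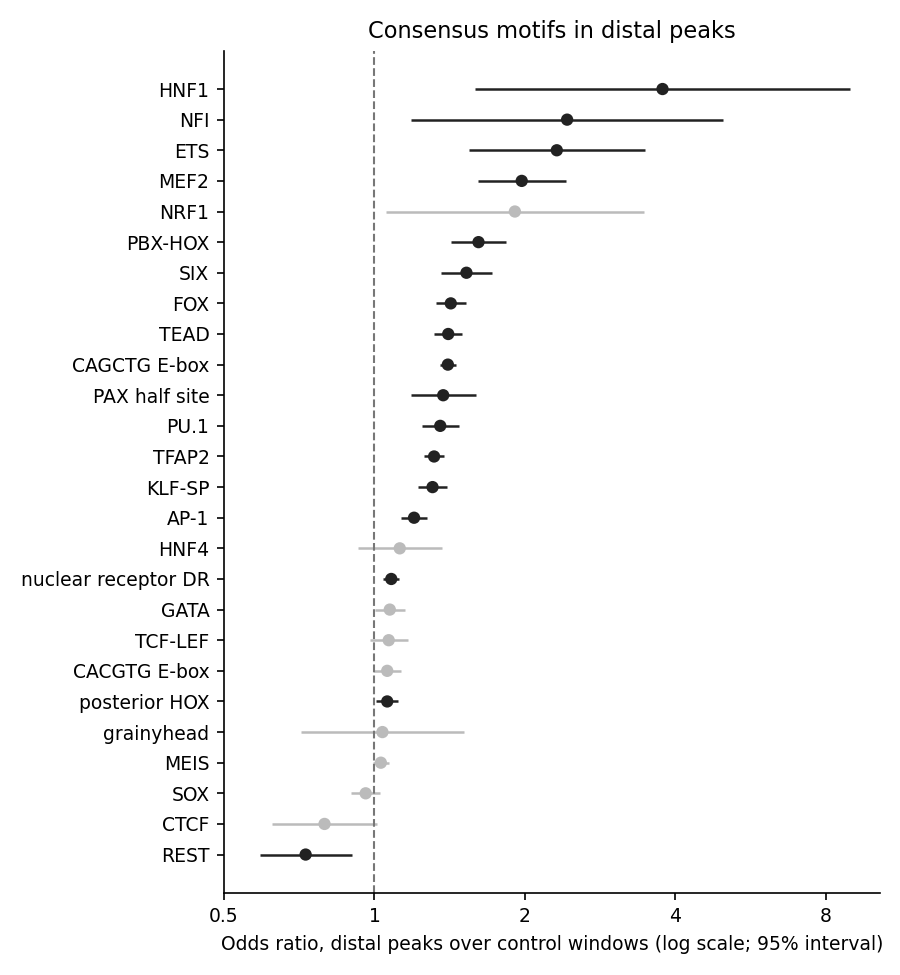
Odds ratio of each of 26 consensus motifs in 500 bp windows of distal replicated peaks over GC-matched control windows (x axis, log scale) with 95% intervals, in black where the adjusted p was under 0.05. HNF1 has the largest ratio, 3.77, with a wide interval, and REST lies below 1 at 0.728.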

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

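1 result was set apart by the rule for signal in data outside the main comparisons. 4 replicated peaks, with enrichments from 2.24 to 31.3, lay on 3 scaffolds without a position in the assembly and entered no comparison. The rule sets them against the 3 that a count of 0 allows, but nothing here gives an expectation of 0, since such scaffolds are part of the genome, so the count is only recorded. Rules for samples far from their group or for differences between groups did not apply to 1 group of 2. The tests of explanations given here were written before their results were seen, but after the patterns themselves had been noticed. The p adjusted over the lists and the control windows with at most 50% repeat were added after seeing the results.

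The first pattern was macrophage and immune promoters, marked in 7 of 13 genes in replicate 2 and 1 of 13 in replicate 1. Cutting replicate 2 to its 62262 strongest peaks by p, as many as replicate 1 had, left 3 of 13, so the length of the peak list is a candidate explanation for most of the difference. More immune cells in replicate 2 could also contribute: among genes unmarked in replicate 1, 6 of 12 list members gained a peak in replicate 2 against 16.99% of other genes (p = 0.00877, Fisher's exact test). This met the p under 0.05 written beforehand, but the list was picked from 24 for its difference, the adjusted p was 0.0702, and ureteric bud genes also gained peaks (4 of 5, adjusted p = 0.0434, exact test), so a gain is not particular to immune genes and the explanation stays open. Aif1 and Cd68 were among the 7 members with a promoter peak in replicate 2. C1qa, C1qb, Ptprc and Lyz2, chosen after their values were seen, had none there. None of the 13 had a peak at a q of 1e-05 or less in replicate 2. These observations do not decide between the explanations.

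The second pattern was peaks of 1 replicate with no partner in the other, 76165 in replicate 2. The result written beforehand as speaking against calls at random places was met, but it does not decide the question. The E-box CAGCTG was in 29.0% of the 63794 distal windows of such peaks and 23.7% of GC-matched windows outside peaks (odds ratio 1.32, p = 2.35e-104, Fisher's exact test). With control windows of at most 50% repeat the odds ratio was 1.23. In these windows 17 of the 26 motifs were more frequent, and SOX (0.864) and REST (0.717) were less frequent. The excess was thus not particular to CAGCTG. Matching was on GC content only, so a general sequence difference from the control windows cannot be told apart. These ratios cover the set as a whole, so random calls among these peaks are not excluded. The windows were not matched on neighbouring pairs of bases. Weak peaks near the calling threshold remain a possible explanation. The share overlapped fell from 76.9% in the strongest 25% of replicate 2 peaks to 10.01% in the weakest, but the 80% set beforehand for the strongest 25% was not reached. A difference in depth or between the pools of embryos was not tested.

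The third pattern was promoter peaks at 9 of 99 genes of 8 lists of other tissues and cell types. Of these, Aif1, Cd68, Nfe2, Tal1, Klf1 and Elavl4 came from the macrophage, erythroid and peripheral neuron lists, which are cell types and not separate organs. A neighbouring gene's promoter accounted for few of the 9 peaks: 11.1% (1 of 9, Mylpf with Tbc1d10b) shared the peak with another protein-coding TSS, where more than 50% had been expected if this were the cause. Among kidney lists 0 of 72 marked genes shared one. Cells of those kinds within the dissected kidneys may contribute, and no biological explanation was tested, since the design has 1 group.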

How the results depend on the processing

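Alternatives added after seeing the data were the test without neighbouring TSS, the control windows with at most 50% repeat and the odds ratio over that of the reversed consensus. No paired analysis was possible because there was 1 group. Where a value changed, the cause was not tested unless the setting itself shows it. Depth is unknown and limits every statement on missing peaks.

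The overlap of replicate 1 by replicate 2 and of replicate 2 by replicate 1 was 60.9% and 28.2% with 50% of the shorter peak, 29.8% and 16.5% with 50% of both, 92.9% and 30.3% at an enrichment of at least 4, and 58.9% and 48.7% with equal numbers of top peaks. At a q of 1e-05 or less the first was 97.4%. The Jaccard index was 33.2% at that q, 33.0% at that enrichment and 37.5% with equal numbers. The Spearman correlation was 0.583 by −log10 p, 0.791 with 50% of both peaks and 0.671 at that q. The share of replicated peaks found in both replicates was 49.5% with 50% of the series-level peak and 46.0% with 50% of both, and of pooled peaks 27.7% and 25.7%.

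The promoter share of peaks was 41.7% at a q of 1e-05 or less, 42.8% at an enrichment of at least 4, 23.4% in the pooled list and 18.95% to 26.2% in single replicates. Windows of 500 bp and 2.5 kb and the share of bases moved it by less than the SD between replicates.

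No called gene list changed direction. Of the 8 lists called with more and the 9 with fewer promoter peaks, only forebrain kept its call in all 9 alternatives, and 3 uncalled lists stayed uncalled. With GC-rich promoters only, the lists with more promoter peaks went from 8 to 0 and those with fewer from 9 to 4. In that setting 9 or fewer members were left in most lists and 71.7% to 71.8% of other genes were marked. The share was 100% for nephron progenitor, renal stroma, endothelium, cell cycle, housekeeping and Hox 9 to 11 genes, 83.3% for Hox 1 to 8, 85.7% for imprinted, 40% for mature tubule, 20.0% for muscle and for pluripotency, and 0% for macrophage, hepatocyte and olfactory receptor genes, all no longer past the threshold. Hox 12 and 13 genes, at 16.7%, passed it. With a 500 bp window erythroid genes passed (15.4%). With 2.5 kb macrophage and muscle genes (23.1% each) and adrenal genes (18.2%) did not. At a q of 1e-05 or less, and likewise at an enrichment of at least 4, early nephron genes passed (75%) and endothelial (69.2%) and imprinted genes (71.4%) did not. In the pooled list peripheral neuron and muscle genes (23.1% each) did not. Without neighbouring TSS early nephron genes passed (75%), and macrophage (15.4%) and pluripotency genes (10%) did not.

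In single replicates the number of lists with fewer peaks was 5 to 10. Shares ranged from 68.8% to 87.5% for ureteric bud, 87.5% to 93.8% for early nephron, 17.6% to 35.3% for mature tubule, 7.69% to 53.8% for macrophage, 7.69% to 38.5% for peripheral neuron, 9.09% to 27.3% for adrenal and 15.4% to 30.8% for erythroid genes. Ureteric bud genes passed in replicate 2 alone, erythroid genes in replicate 1 alone and early nephron genes in each. Calls for mature tubule, macrophage, peripheral neuron and adrenal genes were lost in replicate 2 alone.

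Of the 24 distal results 18 held in all 7 alternatives, 7 of them among the 10 called lists. Housekeeping and Hox 12 and 13 genes did not pass with 20 kb (255 and 729 bp). With 100 kb podocyte genes passed (3199.5 bp), renal stroma did not (2489 bp), and olfactory receptor genes (0 bp) passed as lower, as they did in the pooled list and in each replicate (0 bp). Housekeeping genes did not pass in the pooled list (2043.5 bp). In single replicates renal stroma ranged from 926.5 to 4710.5 bp and muscle from 1453 to 1768 bp, and in replicate 1 alone the first did not pass and the second did.

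Of the 20 longest domains, 6 were among the longest with joining at 4 kb, 5 without joining, 12 in the pooled list and 10 to 11 in single replicates.

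Motifs more frequent in peaks numbered 7 with 200 bp windows and 8 by the odds ratio over that of the reversed consensus, against 16. Less frequent ones numbered 2 with 200 or 1000 bp, by that ratio or with less repeat, 3 against the reversed consensus and 1 to 2 in single replicates, against 1. With 200 bp windows HNF1, PU.1 (1.09), NFI (1.15), ETS (1.23), posterior HOX (1.05), the PAX half-site (1.34) and the nuclear receptor consensus (1.01) no longer passed, and by that ratio HNF1 (4.61) and the PAX half-site (1.06) did not. The direction changed for AP-1 (0.997) and KLF-SP (0.933) with 200 bp, CTCF (1.46) with 1000 bp, posterior HOX (0.881) by that ratio, and MEIS (0.929) and the nuclear receptor consensus (0.939) with less repeat. The ratio against the reversed consensus in the same windows holds no control windows, and the reversal's own base composition by neighbouring pairs differs. That ratio lay on the other side of 1 from the odds ratio for SIX-type (0.930), FOX (0.767), ETS (0.252), SOX (1.69), REST (4.20), CTCF (34.6), the nuclear receptor consensus (0.976) and the PAX half-site (0.697). TEAD and PBX-HOX held in all 7 alternatives run for them. CAGCTG, MEF2 and TFAP2 held in all of the 5 run for them, which were fewer than for TEAD and PBX-HOX.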

Other observations

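The mature tubule member with the strong peak was Hnf1a (chromosome 5, 114967319 to 114971441), and the transporters Slc34a1, Slc12a1 and Slc12a3, chosen after their values were seen, had no promoter peak in any of the replicated or single replicate lists.

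Both sexes had been pooled, and of 6 genes fixed to read this, Ddx3y, Uty and Xist had a replicated promoter peak (5.90, 5.09 and 4.14). Xist had none in replicate 1. The third longest domain spans the 5′ ends of Mrpl23 and of the imprinted H19, whose window held 32055 distal bp, its own non-coding promoter included, and the domains nearest to Igf2r (26285 bp) and Cpa1, beside the imprinted Mest (16963 distal bp), were also among the 20 longest. Whether imprinted genes are more frequent near long domains was not tested.

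A hypothesis written before its test was that distal peaks within 50 kb of nephron progenitor genes may hold a SIX-type consensus more often than other distal peaks, since Six2 is active there. 0 of 57 such windows held one (exact 95% interval 0% to 6.27%) against 2.52% of 27544 other windows (p = 0.406, Fisher's exact test). The windows were too few to tell.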
